A study of Homo sapiens with 4 samples.

How the data were processed

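RNA was sequenced from KTC1 cells, an established human line described in the labels as papillary thyroid cancer cells. The labels give 4 libraries, 2 from cells carrying an empty vector and 2 from cells carrying a vector that expresses SLC6A15. Per the labels' protocols, stable cells of each kind were selected with 200 µg/ml of G418, an antibiotic that kills cells lacking a resistance gene, over 14 days. Messenger RNA was captured on oligo(dT) beads, primed with random hexamers and sequenced on a BGISEQ-500 instrument. The protocols mention no step that keeps the strand of the RNA, so a gene and a gene antisense to it cannot be told apart.

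The submitters' processing notes list HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 and the genome build GRCh38.p12, without saying which step each tool served. The alignment settings, the annotation release and any filter on genes are not given in the sources used here. Per the file headers, each deposited table holds 1 expression value per gene with 2 decimals, and the header names no unit. The deposited values were read as FPKM, fragments per kilobase of transcript scaled to the library's total of mapped fragments. The reading rests on the values: they sum to between 480127 and 489580 per library over 16872 listed genes even though abundant ribosomal and glycolytic genes are among them, which rules out TPM taken over the listed genes, and RSEM writes FPKM. The unit remains a reading, not a statement of the submitters. With another unit the weight of the pseudocount and of the filter on low values would differ.

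The design fixed beforehand called for a test on counts, or for limma if only normalised values were at hand. The tables hold no counts, so the second branch applied. Values were transformed to log2(value + 1), genes with a value of 1 or more in at least 2 libraries were kept, and limma 3.58.1 in R 4.3.3 was fitted with group as the single term and its empirical Bayes variance without a trend on expression. P-values were adjusted by the Benjamini-Hochberg method over the 11433 genes that passed the filter, with a threshold of 0.05. Fold changes are given on the log2(value + 1) scale, SLC6A15 minus Vector, which understates the change of genes with low values. SE is limma's moderated standard error. No library scaling was added to the deposited values in this fit. The median log2 fold change over all genes tested was -0.0093.

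Gene numbers and symbols come from the tables. Of the listed genes, 16631 gene numbers were found in the RefSeq table used here and 16280 of those are annotated as protein coding. Because 642 symbols are older names and 26 have been turned into dates, list members were matched through the gene number. Coordinates are from GENCODE 29 on GRCh38 and count from 1. RSEM shares ambiguous fragments out between similar transcripts, so values of genes with near-identical copies or read-through transcripts carry additional uncertainty.

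Before the data were examined, 34 gene lists, the alternatives and the rule for naming genes were written down. The named genes are SLC6A15 and ICAM1; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with the groups not overlapping and a mean of at least 5 in the higher group; and, from each list, the 4 members past the threshold with the largest absolute change or, where none passed, the most highly expressed members. Other genes are named only as members of a list or where the text says that they were chosen after their values were seen. A listed gene counts as measured if it passed the filter. Lists with 5 or more measured members were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over 29 lists. Camera was run again with the correlation estimated from the data, which leaves 2 residual degrees of freedom and so little power. Where the estimate lies well above 0.01, the preset can make camera's p-values too small. The fry test was also run. It asks whether a list's genes move on balance in one direction and does not compare them with other genes. SLC6A15 is in no list. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Lists overlap, so a gene can count in more than one.

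The depth is not stated in the tables. Fragments per library were estimated from the spacing of low values among genes with a single transcript, where values cluster at whole multiples of 1 fragment. The estimate was 16000000 and 17000000 mapped fragments for the Vector libraries and 16700000 and 17200000 for the SLC6A15 libraries, and it ranged from 15400000 to 18600000 with the fragment length assumed. The clustering score was 0.336 to 0.434, against at most 0.226 in 20 shuffles per library. Not every value was a whole multiple, so no counts were rebuilt. At these depths a value of 1 corresponds to about 16 to 17.2 fragments per kilobase of transcript.

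The limma procedure was tested on simulated data modelled on this comparison, with 11365 genes, 200 changed genes in each of 5 simulations and 2 libraries per group. It recovered 53.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.2% of those changed 4-fold, and 6.02% of calls were false. A planted list was found in 5 of 5 simulations and an unchanged list in 0, at camera's unadjusted p under 0.05. The simulated noise was independent between genes and libraries and drawn from limma's own fitted variances. In the real libraries the replicate differences of the 2 groups correlated at 0.387 across genes. The simulated error rates therefore show how the procedure works under its own assumptions and do not carry over to these libraries.

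The alternatives tried were other scalings, other filters, limma-trend, a pseudocount of 0.1, SLC6A15 left out, the replicate number as a block and each library left out in turn. A filter at a value of 5 was added after the data had been seen. Random lists were drawn with Python 3.11.15 and numpy 2.4.6. None of the 13 listed mitochondrially encoded genes was matched to a deposited gene, so that list could not be analysed. Groups of 2 libraries are too small for a test of outlying libraries.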

Results

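Polyadenylated RNA of KTC1 papillary thyroid cancer cells was profiled in 2 groups of 2 libraries: cells stably carrying an empty vector (Vector) and cells stably expressing SLC6A15 from a vector (SLC6A15). SLC6A15 is a sodium-dependent transporter of neutral amino acids, chiefly branched-chain amino acids and proline. The tables list 16872 genes, of which 812 have a value of 0 in all 4 libraries, and values are read as FPKM. Estimated depth was 16000000 and 17000000 mapped fragments in Vector and 16700000 and 17200000 in SLC6A15 cells. Between 11263 and 11400 genes had a value of 1 or more in a library. Pearson's r across genes, which are not independent replicates, was 0.9959 between the replicates of each group and 0.9843 to 0.9931 between libraries of different groups. Among 1652 genes with a mean value of 50 or more and a known transcript length, the log2 difference between replicates had an SD of 0.12 in Vector and 0.114 in SLC6A15 cells. This lay above the 0.0556 and 0.055 that counting alone would give at the estimated depth and the median transcript length, so the replicates were kept as separate libraries. The labels say neither whether the replicates are separate cultures nor how many stable selections each group holds. P-values therefore measure the spread between these libraries, which may be technical.

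The comparison asks which transcripts differ when SLC6A15 is overexpressed. SLC6A15 itself (gene 55117, chromosome 12, positions 84859488 to 84913615 on the minus strand, GRCh38) had values of 0.17 and 0.25 in the Vector libraries and 22.0 and 23.81 in the SLC6A15 libraries, as the labels of all 4 state. The means were 0.21 ± 0.057 (SD, n = 2) and 22.9 ± 1.28 (SD, n = 2), a ratio of 109 that rests on a few fragments in the Vector libraries. On the log2(value + 1) scale the difference was 4.30 (SE 0.077, limma adjusted p = 2.38e-05). The value can hold transcripts of the vector as well as of the cell's own gene.

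In SLC6A15 cells, 13 of 32 targets of the amino acid response rose, most of them genes for amino acid uptake and synthesis, as did 6 of 21 YAP/TAZ targets. By contrast, 6 of 22 cholesterol synthesis genes, 4 of 12 epithelial markers and 7 of 20 genes downstream of MAPK signalling fell. Of 11433 genes tested, 177 were higher and 316 lower in SLC6A15 cells (limma, Benjamini-Hochberg adjusted p under 0.05), among them 17 higher and 23 lower by 2-fold or more. Among genes with a mean of at least 5 in the higher group, the largest rises after SLC6A15 were those of EDN2, DYSF and EFEMP1. EDN2 encodes the vasoconstrictor peptide endothelin 2 (0.75 to 5.13, log2 fold change 1.81, SE 0.078). It was below 1 in both Vector libraries and passed the filter through the SLC6A15 libraries alone, which fixes its direction. DYSF encodes the membrane repair protein dysferlin (4.04 to 14.7, 1.64) and EFEMP1 the matrix protein fibulin-3 (1.76 to 7.02, 1.54). The carboxypeptidase gene CPA4 (1.404), the growth factor receptor gene PDGFRB (1.37), ADAMTSL4 (1.27), the podoplanin gene PDPN (1.05) and 3 genes for secreted matrix-associated proteins, FSTL1 (1.04), CCDC80 (1.04) and the biglycan gene BGN (1.02), followed. FSTL1 went from 55.6 ± 0.064 to 115.7 ± 5.49 (mean and SD, n = 2 each). The long non-coding genes C7orf69 (1.51) and C6orf99 (1.04) also rose. C7orf69 is annotated as antisense to another gene and its value is uncertain without strand.

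With the same minimum mean of 5 in the higher group, the largest fall was that of PPP1R1A, which encodes an inhibitor of protein phosphatase 1 (11.4 to 1.71, log2 fold change -2.20, SE 0.14, limma adjusted p = 0.0055). It was followed by LGR5, a receptor gene that amplifies Wnt signalling (20.1 to 4.02, -2.06), the carbonic anhydrase gene CA12 (33.3 to 7.42, -2.05) and ANGPTL4, which encodes an inhibitor of lipoprotein lipase (43.4 to 11.2, -1.82). CA12 had values of 40.82 and 25.74 in Vector and 9.81 and 5.02 in SLC6A15 libraries (SE 0.31, limma adjusted p = 0.030). ANGPTL4 had values of 56.5 and 30.24 in Vector and 13.49 and 8.89 in SLC6A15 libraries (SE 0.31, limma adjusted p = 0.038). BGLAP (-1.59, SE 0.30, limma adjusted p = 0.047) shares exons with a read-through transcript and is uncertain. BIRC3 (-1.49), the reelin gene RELN (-1.46), the organic anion transporter gene SLCO4A1 (-1.36), the tenascin C gene TNC (-1.29, SE 0.25, limma adjusted p = 0.048), TMEM163 (-1.27) and the claudin 1 gene CLDN1 (-1.26) fell as well. SPP1, which encodes the secreted phosphoprotein osteopontin, was among the most abundant of these and went from 560.7 ± 42.2 to 230.4 ± 24.2 (mean and SD, n = 2 each; -1.28). All of these genes but CLDN1 were lower in replicate 2 than in replicate 1 of both groups, the direction of the group difference. ICAM1, an adhesion receptor of the immunoglobulin superfamily (chromosome 19, positions 10270835 to 10286615, GRCh38), had values of 8.97 and 7.68 in Vector and 5.35 and 5.31 in SLC6A15 libraries (log2 fold change -0.56, SE 0.087, limma adjusted p = 0.032).

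**Figure D1:**
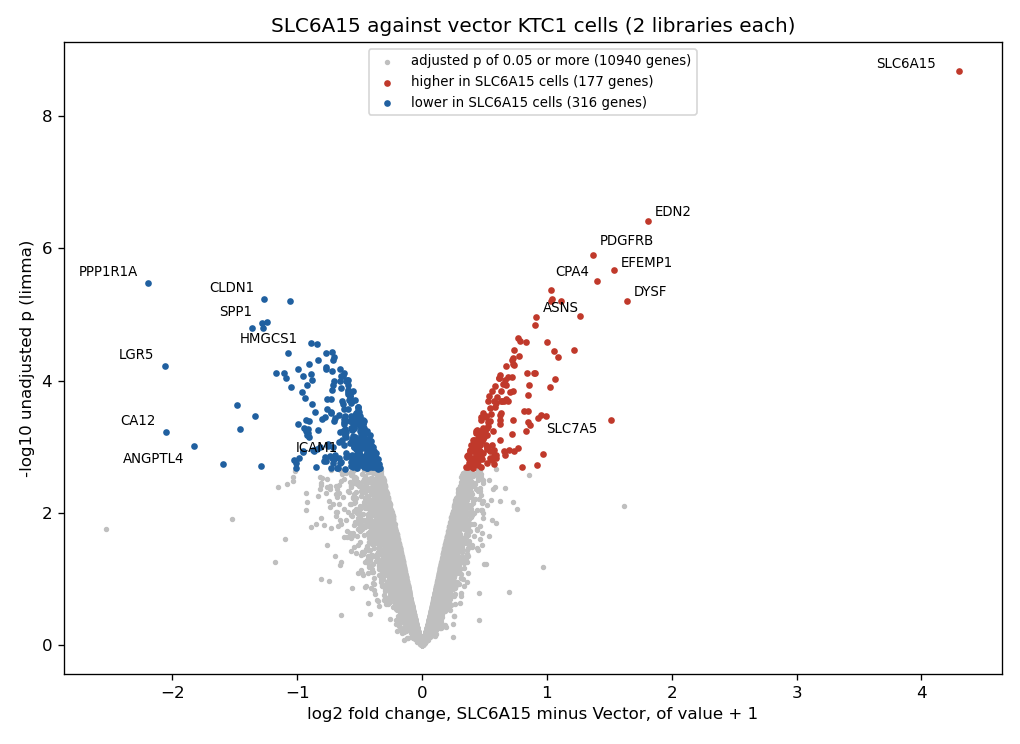
Each point is 1 of 11433 genes, with the log2 fold change of value + 1 (SLC6A15 minus Vector) on the horizontal axis and -log10 of limma's unadjusted p on the vertical axis. Red points are the 177 genes that were higher and blue points the 316 that were lower at an adjusted p under 0.05, and SLC6A15 stands apart at 4.30.

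The number of genes past the threshold depends on single libraries: it was 967 without SLC6A15 replicate 1 and 250 without SLC6A15 replicate 2, against 493 with all 4. With Vector replicate 1 or Vector replicate 2 left out, SLC6A15 was the 1 gene past limma's threshold (1538 and 2438 genes at an unadjusted p under 0.05), as it was without a filter on low values (3093 at an unadjusted p under 0.05), and every gene past the threshold that could still be tested kept its direction in these 3 fits. The counts of list members given below move likewise: 37 listed genes rose and 35 fell with all 4 libraries, 45 and 81 without SLC6A15 replicate 1, and 0 without either Vector library.

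Genes that respond to amino acid shortage through the transcription factor ATF4 were higher in SLC6A15 cells. Of 32 measured targets 13 rose, 1 fell and 18 did not pass (8 rose and 0 fell without SLC6A15 replicate 2; 17 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.32. The list was higher than other genes by camera (adjusted p = 1.97e-08), and adjusted p = 0.48 with an estimated correlation. Its fry adjusted p was 0.0016. Among the other lists that camera called, fry passed for the epithelial markers (adjusted p = 0.022) and for no other, with adjusted p between 0.062 and 0.51. SLC7A5 and SLC3A2, which together encode the heterodimeric exchanger of large neutral amino acids, went from 161.8 ± 17.1 to 309.2 ± 49.0 (log2 fold change 0.93, SE 0.13, limma adjusted p = 0.027) and from 91.9 ± 10.6 to 166.7 ± 22.2 (0.85, SE 0.12, adjusted p = 0.027; means and SD, n = 2 each). The asparagine synthetase gene ASNS went from 21 ± 0.74 to 40.4 ± 0.82 (0.91, SE 0.069, limma adjusted p = 0.0083), and STC2, which encodes stanniocalcin 2, rose by 0.84. The other targets that rose were PCK2, ALDH1L2, PHGDH, JDP2, PSAT1, SLC7A11, MTHFD2, CTH and PYCR1, most of them enzymes of serine, one-carbon, cysteine and proline metabolism. CEBPB fell (-0.36). The stress genes DDIT3 (-0.04), TRIB3 (-0.01) and SESN2 (-0.08) and ATF4 itself (0.08) did not pass the test. Between replicates of a group the list's median differed by 0.0048 in Vector and by 0.0081 in SLC6A15 cells. It ranged from 0.25 to 0.37 as each library was left out. Single members did differ between replicates. SLC7A5 had values of 149.67 and 173.83 in Vector and 274.58 and 343.81 in SLC6A15 libraries. SLC3A2 was likewise higher in replicate 2 of both groups, whereas STC2 was lower.

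Amino acid transporters outside the SLC6 family had 4 genes that rose, 1 that fell and 13 that did not pass among 18 measured. Adjusted over the list alone 5 rose and 3 fell (median 0.07, camera adjusted p = 0.082). The median ranged from 0.050 to 0.13 as each library was left out. It was 0.0094 with values scaled to the same total and -0.024 without a filter on low values. SLC7A5, SLC3A2 and the cystine transporter gene SLC7A11 (0.49) rose, as did SLC1A5, and SLC3A1 fell (-0.53). SLC3A1 passed the filter through the Vector libraries alone (0.76 and 0.56 in SLC6A15 libraries), so its direction was fixed. Of the SLC6 family 3 members were measured and none passed (1 rose adjusted over the list alone). The taurine transporter gene SLC6A6, the most highly expressed of them, was at 121.0 ± 1.67 and 128.0 ± 16.1 (0.07, SE 0.098). Its sign depends on 1 library, since the difference was -0.053 without SLC6A15 replicate 1. Cytoplasmic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, had 19 of 20 members above 0 with a median of 0.17. None passed over all genes, 8 were higher adjusted over the list alone, and camera gave an adjusted p of 3.46e-06, with adjusted p = 0.51 with an estimated correlation. That count of 0 depends on the fit, since 5 rose with limma-trend and 6 with the replicate number as a block. The median of the synthetases was also higher in replicate 2 than in replicate 1, by 0.044 in Vector and 0.068 in SLC6A15 cells. The isoleucyl-tRNA synthetase gene IARS was at 148.8 ± 2.81 and 178.2 ± 8.79 (0.26, SE 0.072, limma adjusted p = 0.10). Of 21 genes of branched-chain amino acid and proline metabolism, the proline synthesis gene PYCR1 rose (0.35, SE 0.068, limma adjusted p = 0.048) and 20 did not pass (1 rose adjusted over the list alone, median -0.01 and mean -0.004 with camera pointing upward, adjusted p = 0.75; the median ranged from -0.062 to 0.021 as each library was left out). Genes of the unfolded protein response in the endoplasmic reticulum did not stand apart: 0 of 20 passed, over all genes or over the list alone, the median was -0.05 (camera adjusted p = 0.41), and the calreticulin gene CALR was at 914.9 ± 7.27 and 843.5 ± 10.9 (-0.12).

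Cholesterol synthesis genes were lower in SLC6A15 cells. Of 22 measured genes 21 had a negative difference, 6 fell, 0 rose and 16 did not pass (15 fell adjusted over the list alone), with a median of -0.32 (camera adjusted p = 5.73e-08, and adjusted p = 0.53 with an estimated correlation). TM7SF2, a sterol reductase gene, went from 15.3 ± 0.90 to 7.20 ± 1.01 (-0.997, SE 0.10, limma adjusted p = 0.016). HMGCS1, which encodes the enzyme before the rate-limiting step, went from 25.4 ± 0.092 to 15.2 ± 0.49 (-0.70), MSMO1 from 65.4 ± 0.57 to 41.2 ± 1.24 (-0.65) and HSD17B7, which has a similar pseudogene, from 25.7 ± 0.16 to 17.9 ± 0.72 (-0.50; means and SD, n = 2 each). INSIG1 and SQLE fell too. Between replicates the list's median moved the other way, by 0.08 in Vector and 0.13 in SLC6A15 cells (replicate 2 minus replicate 1). Of 24 glycolysis and hypoxia genes 0 passed over all genes or over the list alone (median -0.13, camera adjusted p = 0.13), and GAPDH was at 4928 ± 1.75 and 4774 ± 106.6 (-0.05). That list's median also differed between replicates, by -0.19 in Vector and -0.12 in SLC6A15 cells. It was -0.039 without Vector replicate 1 and -0.014 without SLC6A15 replicate 2, whereas camera called the list lower without Vector replicate 2 (-0.19, adjusted p = 0.0013) and without SLC6A15 replicate 1 (-0.18, adjusted p = 0.0065, with 4 genes that fell). Among 21 NRF2 targets, which serve antioxidant defence, SLC7A11 rose, the glutathione reductase gene GSR fell (-0.47, SE 0.069, limma adjusted p = 0.028) and 19 did not pass (1 rose and 6 fell adjusted over the list alone, median -0.10, camera adjusted p = 0.10, but -0.17 and 0.021 without Vector replicate 1 and -0.13 and 0.029 without SLC6A15 replicate 2).

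Several epithelial markers fell and a few mesenchymal markers rose. Of 12 measured epithelial markers 4 fell, 0 rose and 8 did not pass (6 fell adjusted over the list alone, median -0.33, camera adjusted p = 0.0075, and adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.022). The tight junction genes CLDN1 (12.9 ± 1.202 to 4.78 ± 0.23, -1.26, SE 0.086), TJP3 (1.44 ± 0.28 to 0.31 ± 0.014, -0.89, SE 0.094) and OCLN (3.98 ± 0.34 to 2.37 ± 0.13, -0.56, SE 0.079) and the mucin gene MUC1 (8.68 ± 0.25 to 5.79 ± 0.65, -0.51, SE 0.087) fell. OCLN has a partial copy nearby and is less certain. A marker can pass the filter on low values through a single group, and its direction is then fixed. TJP3 passed through the Vector libraries alone, with 1.24 and 1.64 in Vector and 0.32 and 0.30 in SLC6A15 libraries. KRT18 was at 161.2 and 157.0 (-0.04), and CDH1 and EPCAM were below 1 in all 4 libraries. Of 17 mesenchymal markers 3 rose, 0 fell and 14 did not pass, with 10 positive and 7 negative differences (5 rose adjusted over the list alone, median 0.12, camera adjusted p = 0.026, and adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.15). SNAI2, which encodes the transcription factor Slug, went from 9.69 ± 0.71 to 20.4 ± 1.57 (0.9996, SE 0.087, limma adjusted p = 0.012), and TAGLN (0.74) and TGFBI (0.50) rose as well. Both list calls depend on single libraries: without Vector replicate 2 camera gave an adjusted p of 0.091 for the epithelial (median -0.20) and 0.18 for the mesenchymal list (median 0.06), and without SLC6A15 replicate 1 it gave 0.40 for the mesenchymal list (median 0.08). The epithelial median was -0.10 without Vector replicate 1 (adjusted p = 0.047); without either Vector library 10 of the 12 epithelial markers passed the filter. The epithelial median was -0.04 without a filter on low values (adjusted p = 0.20), and the mesenchymal median was 0.05 with a filter at a value of 5 (adjusted p = 0.33).

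Adhesion molecules went both ways. Among 15 measured, the melanoma cell adhesion molecule gene MCAM (16.2 ± 0.86 to 31.2 ± 0.16, 0.90, SE 0.071), CADM1 (0.67) and ALCAM (0.38) rose, CADM4 (-0.91), ICAM1 (-0.56), CD58 (-0.55) and F11R (-0.43) fell, and 8 did not pass (3 rose and 5 fell adjusted over the list alone, median -0.13, camera adjusted p = 0.40). The median was -0.046 without Vector replicate 1, -0.22 without Vector replicate 2 and -0.25 without SLC6A15 replicate 1. CADM1 passed the filter through the SLC6A15 libraries alone and CADM4 through the Vector libraries alone, so their directions were fixed. No integrin of 10 passed, over all genes or over the list alone (median -0.17, camera adjusted p = 0.18, but 0.038 without Vector replicate 2; 3 fell without SLC6A15 replicate 1). The integrin beta 1 gene ITGB1 was at 428.6 ± 24.6 and 516.5 ± 5.98 (0.27). Of 25 matrix protein genes 3 rose, 3 fell and 19 did not pass (6 rose and 9 fell adjusted over the list alone, median -0.11, camera adjusted p = 0.49). That median ranged from -0.032 without SLC6A15 replicate 2 to -0.22 without Vector replicate 2, and it differed by -0.17 between the Vector and by -0.12 between the SLC6A15 replicates. The thrombospondin gene THBS1 went from 225.7 ± 8.02 to 386.4 ± 18.5 (0.77, SE 0.074, limma adjusted p = 0.014) and COL5A1 rose (0.60), whereas TNC (-1.29) and the lumican gene LUM (-0.65) fell. Among 18 matrix proteases and inhibitors MMP24 (0.69) and ADAMTS1 (0.66) rose and 16 did not pass (4 rose and 4 fell adjusted over the list alone, median -0.01 and mean 0.02, camera adjusted p = 0.73; the median ranged from -0.043 to 0.011 as each library was left out).

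**Figure D2:**
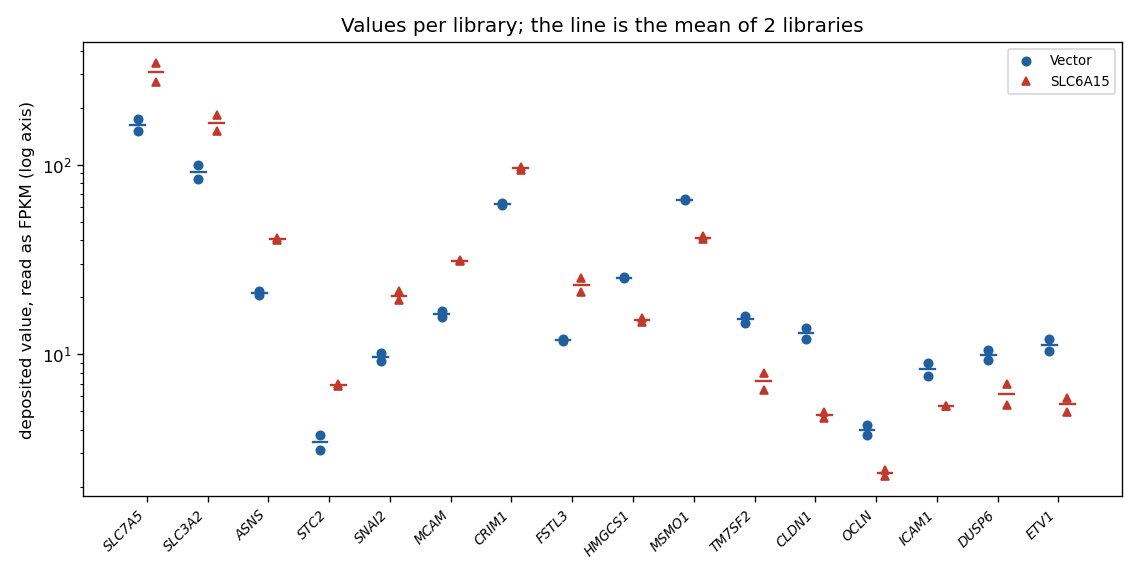
Deposited values, read as FPKM, on a log axis for 16 genes in each Vector library (circles) and SLC6A15 library (triangles), with a line at the mean of 2 libraries. The groups do not overlap for any of these genes, which were taken because they passed the test.

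Several genes downstream of MAPK signalling fell. Of 20 measured 7 fell, 1 rose and 12 did not pass, with 15 negative differences (11 fell and 2 rose adjusted over the list alone, median -0.43, camera adjusted p = 9.84e-04, and adjusted p = 0.61 with an estimated correlation). The transcription factor gene ETV1 went from 11.2 ± 1.16 to 5.43 ± 0.66 (-0.93, SE 0.11, limma adjusted p = 0.017), IER3 from 92.0 ± 2.53 to 55.8 ± 4.38 (-0.71) and DUSP6, which encodes a phosphatase that inactivates ERK, from 9.93 ± 0.85 to 6.17 ± 1.10 (-0.62), and the cytokine gene IL11 rose (0.97). IL11 passed the filter through the SLC6A15 libraries alone (0.28 and 0.42 in Vector libraries), so its direction was fixed. SPRY4, ETV4, DUSP5 and SPRY2, further ERK-induced genes, fell. The number that fell was 11 without SLC6A15 replicate 1 and 3 without SLC6A15 replicate 2. NF-kappaB and cytokine genes had 3 of 20 that fell, 0 that rose and 17 that did not pass (9 fell and 1 rose adjusted over the list alone, median -0.38, camera adjusted p = 3.10e-04, and adjusted p = 0.48 with an estimated correlation). BIRC3, an inhibitor of apoptosis, went from 14.5 ± 2.13 to 4.61 ± 1.51 (-1.49, SE 0.19, limma adjusted p = 0.022), and the chemokine gene CXCL2 (-0.83) and IRAK2 (-0.72) fell. Without SLC6A15 replicate 1, 9 fell. The median of this list was -0.19 without a filter and -0.20 with a filter at a value of 5. Among 30 interferon-stimulated genes 29 had a negative difference and none passed over all genes (5 fell adjusted over the list alone, median -0.21, camera adjusted p = 1.05e-05, and adjusted p = 0.51 with an estimated correlation). The count of 0 depends on the fit, since 3 fell with limma-trend and 12 with the replicate number as a block. The median ranged from -0.27 to -0.18 as each library was left out. IFITM3 was at 551.2 ± 32.5 and 493.2 ± 12.4 (-0.16). Of 15 antigen presentation genes HLA-F fell (-0.42, SE 0.065, limma adjusted p = 0.032; its sequence resembles other HLA genes) and 14 did not pass (4 fell without SLC6A15 replicate 1, 8 fell adjusted over the list alone, median -0.25, camera adjusted p = 3.10e-04, and adjusted p = 0.48 with an estimated correlation). The medians of these 4 lists were also lower in replicate 2 than in replicate 1 of each group, by between -0.04 and -0.13.

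YAP/TAZ targets, which respond to cell shape and tension, included several that rose. Of 21 measured 6 rose, 1 fell and 14 did not pass, with 17 positive differences (3 rose without SLC6A15 replicate 2; 10 rose and 1 fell adjusted over the list alone, median 0.23, camera adjusted p = 1.05e-05, and adjusted p = 0.48 with an estimated correlation). FJX1 (13.9 ± 1.22 to 23.7 ± 2.68, 0.73, SE 0.10), CRIM1 (61.9 ± 1.19 to 95.6 ± 2.24, 0.62, SE 0.067) and the growth factor gene TGFB2 (22.5 ± 0.42 to 34.2 ± 0.70, 0.59, SE 0.067) rose, and the ectonucleotidase gene NT5E fell (-0.87). Among 19 TGF-beta targets 5 rose, 1 fell and 13 did not pass (6 rose and 3 fell adjusted over the list alone, median 0.04, camera adjusted p = 0.14). The median ranged from -0.031 without Vector replicate 1 to 0.099 without Vector replicate 2. The activin antagonist gene FSTL3 (0.91), TAGLN (0.74), TGFB2 (0.59) and PMEPA1 (0.56) rose, and ID2 fell (-0.52). None of 18 immediate early genes passed (1 rose adjusted over the list alone, median 0.01, camera adjusted p = 0.54; without SLC6A15 replicate 1, 2 rose and 1 fell, and without SLC6A15 replicate 2 the median was -0.019). CYR61, also a YAP/TAZ target, was at 171.3 ± 6.34 and 220.9 ± 9.42 (0.36, SE 0.073, limma adjusted p = 0.052).

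No proliferation gene passed the test, over all 11433 genes or over the list of 45 alone, although 44 of 45 had a positive difference (median 0.21, camera adjusted p = 1.35e-08, and adjusted p = 0.72 with an estimated correlation). The difference was about the size of that between replicates: the same median was 0.22 higher in Vector replicate 2 than in Vector replicate 1, and 0.17 higher in SLC6A15 replicate 2 than in SLC6A15 replicate 1. The list's median was 0.094 without Vector replicate 1, 0.094 without SLC6A15 replicate 2 and 0.31 without Vector replicate 2. With limma-trend 2 proliferation genes rose over all genes, and with the replicate number as a block 9 did. The ubiquitin-conjugating enzyme gene UBE2C was at 134.6 and 153.8 in Vector and 146.1 and 181.1 in SLC6A15 libraries. Heat shock genes had 0 of 16 past the threshold (2 rose and 1 fell adjusted over the list alone, median 0.07, camera adjusted p = 0.040, and adjusted p = 0.72 with an estimated correlation), HSPA8 was at 1142 ± 94.4 and 1321 ± 117.5 (0.21), and the median differed between replicates by 0.13 in Vector and 0.09 in SLC6A15 cells. That call was lost without Vector replicate 1 (median 0.026, adjusted p = 0.27), without SLC6A15 replicate 2 (median 0.016, adjusted p = 0.12) and without a filter (adjusted p = 0.16), and the median was 0.14 without Vector replicate 2 and without SLC6A15 replicate 1. Of 77 cytoplasmic ribosomal protein genes 66 had a positive difference and 0 passed, over all genes or the list alone (median 0.06, camera adjusted p = 0.0013, and adjusted p = 0.72 with an estimated correlation), with a median of 0.034 without Vector replicate 1, while RPS27, the most abundant, had a difference of -0.06. No p53 target of 27 passed by either adjustment (median -0.03, from -0.059 to 0.047 as each library was left out, camera adjusted p = 0.88), with PLK2 at 241.3 ± 7.83 and 282.8 ± 0.21 (0.23). No nuclear oxidative phosphorylation gene of 46 passed by either adjustment (median -0.01, from -0.038 to 0.031 as each library was left out, with camera pointing upward, adjusted p = 0.91), with COX7C at -0.26. None of 17 replication-dependent histone genes, whose level in such libraries reflects how RNA was selected, passed over all genes (1 rose adjusted over the list alone, median 0.10, camera adjusted p = 0.32), with HIST1H2BK at 0.10. The histone median was -0.079 without SLC6A15 replicate 1 (1 rose and 3 fell) and 0.013 without Vector replicate 2, and camera called the list higher without SLC6A15 replicate 2 (0.12, adjusted p = 0.029).

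**Figure D3:**
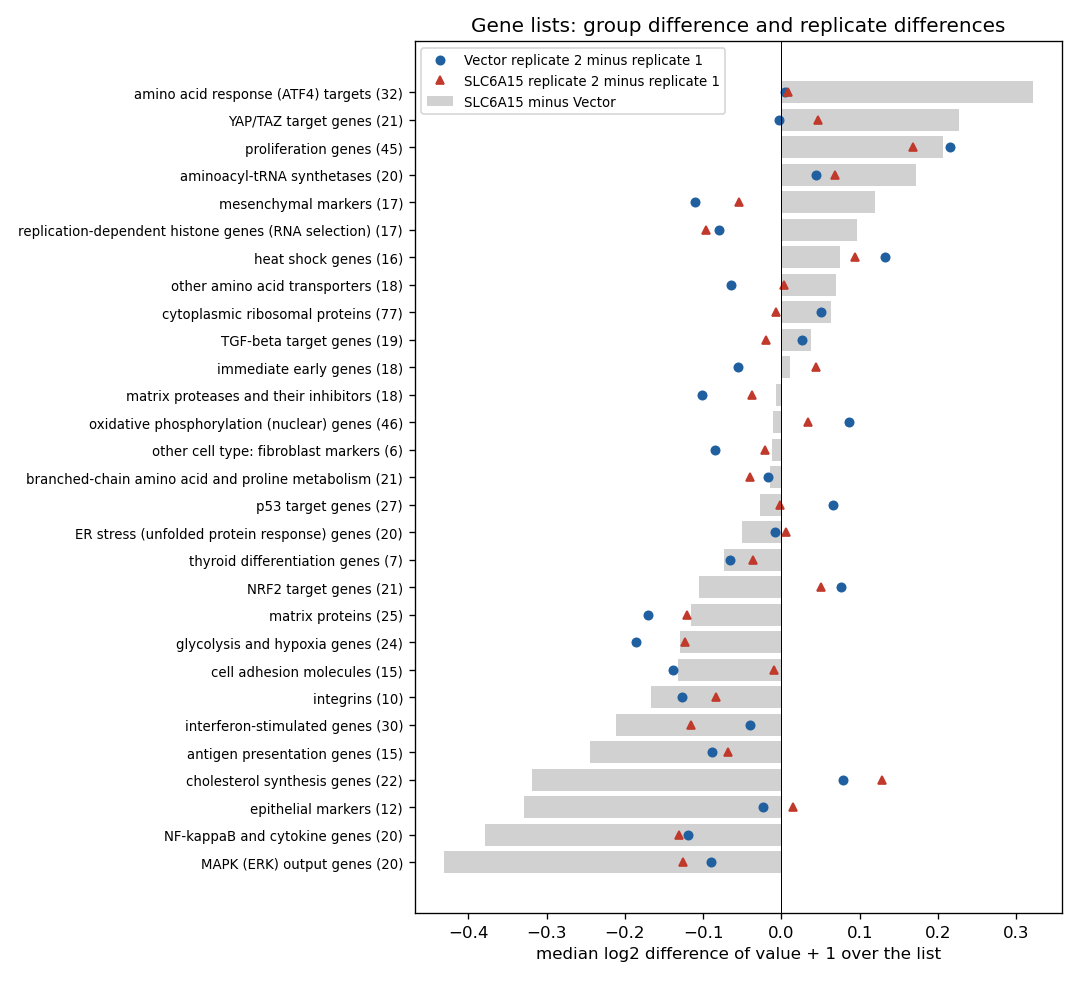
Median log2 difference of value + 1 for 29 lists, with the number of measured genes in parentheses: bars give SLC6A15 minus Vector, circles Vector replicate 2 minus replicate 1, and triangles SLC6A15 replicate 2 minus replicate 1. For ATF4 targets the bar reaches 0.32 with both replicate differences near 0, and for proliferation genes the replicate differences of 0.22 and 0.17 are about as long as the bar of 0.21.

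Of 21 listed thyroid differentiation genes 18 were matched to a deposited gene and 7 were measured, and TG and TSHR were below 1 in all 4 libraries. None passed over all genes (1 rose and 1 fell adjusted over the list alone, median -0.07, camera adjusted p = 0.41). With limma-trend 1 rose and 1 fell over all genes. The median ranged from -0.11 without Vector replicate 1 to -0.049 without Vector replicate 2. The thyroid transcription factor gene PAX8 was at 187.2 ± 15.7 and 134.1 ± 11.9 (-0.48, SE 0.096, limma adjusted p = 0.053). The lists for other cell types held 17 leukocyte, 13 endothelial, 13 fibroblast and 16 neural and melanocytic markers. Of those matched to a deposited gene, 11 of 13 leukocyte, 9 of 10 endothelial, 3 of 9 fibroblast and 9 of 12 neural and melanocytic markers were below 1 in each library. Of the leukocyte markers none of the 2 measured passed by either adjustment, and LAPTM5 was at 154.3 ± 9.14 and 168.4 ± 6.33 (0.13). The endothelial marker ENG, the 1 measured, was at 104.9 ± 4.33 and 88.9 ± 1.86 (-0.24, limma adjusted p = 0.12 over all genes, and 0.015 over the list alone, where it fell). Of 6 measured fibroblast markers PDGFRB and PDPN rose, LUM and FBLN1 (-0.49) fell and 2 did not pass (3 rose and 3 fell adjusted over the list alone, median -0.01 and mean 0.21, the median ranging from -0.32 to 0.037 as each library was left out, camera adjusted p = 0.45, fry adjusted p = 0.022 upward). COL3A1 was listed at 0 in each library. Of 3 measured neural and melanocytic markers TUBB3 rose (0.52) and MBP fell (-0.61), over all genes and over the list alone, and 1 did not pass.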

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

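The filter at a value of 5 was chosen after seeing the data; all other alternatives were planned. SLC6A15 stayed past the threshold in all 9 alternatives that gave it a value, with log2 fold changes from 4.26 to 6.22 (the latter with a pseudocount of 0.1). It has no value when a SLC6A15 library is left out, because it then fails the filter, or when it is left out itself.

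Without a filter on low values, 1 gene was higher and 0 lower (1 and 0 by 2-fold or more, listed genes 0 rose and 0 fell), against 177 and 316. With a pseudocount of 0.1 the counts were 75 and 80 (26 higher by 2-fold or more; 17 listed genes rose and 10 fell). With limma-trend 483 genes and 61 listed genes fell. With a filter at a value of 5, 11 genes were higher by 2-fold or more. The cause was not tested, except that fewer genes are tested under that filter. Leaving out each library in turn gave 1 to 272 higher and 0 to 695 lower genes, 1 to 16 and 0 to 67 by 2-fold or more, and 0 to 45 listed genes that rose and 0 to 81 that fell; the lone library of a group is assumed to vary like the other group. SLC6A6, not past the threshold, ranged from -0.053 to 0.20 in these fits. Both other scalings kept the counts within 1.5 times. In each alternative, those of the 493 genes past the threshold that could still be tested had the same direction. This adds little. Other filters, limma-trend, SLC6A15 left out and the block leave each fold change as it was. Fits with a library left out reuse the libraries that gave these genes. The same holds for the directions given above for the fits without a filter or without a Vector library.

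The replicate number as a block gave 549 higher and 1056 lower genes, with 77 listed genes that rose and 112 that fell. The labels share only the numbers. The replicate differences of the groups correlated at 0.387 across genes, 2 pairs cannot show a pairing, and the block ended the call for the mesenchymal list (adjusted p = 0.080) and gave one for glycolysis and hypoxia genes (0.0064).

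With an estimated correlation 0 lists were higher and 0 lower, against 7 and 6. The estimate was 0.953 for proliferation, 0.484 for heat shock, 0.447 for cholesterol and 0.274 for MAPK genes. It was 0.231 for tRNA synthetases, 0.218 for ribosomal and 0.173 for interferon-stimulated genes. For these lists the preset of 0.01 can make camera's p-values too small. The estimate lay between -0.055 and 0.050 for the ATF4, YAP/TAZ, NF-kappaB, antigen presentation, epithelial and mesenchymal lists. In the other alternatives the calls for ATF4 targets, tRNA synthetases, YAP/TAZ targets, proliferation, ribosomal, cholesterol, NF-kappaB, interferon-stimulated, antigen presentation and MAPK genes were kept. Besides the epithelial, mesenchymal and heat shock calls that were lost, some fits with a library left out or another filter gave a call for amino acid transporters, glycolysis and hypoxia genes, integrins, TGF-beta targets, NRF2 targets or histone genes. Of 67 named genes past the threshold besides SLC6A15, all 67 lost the call without a filter and all 64 with a value lost it without either Vector library. In the other alternatives between 0 and 30 lost it, the most with a pseudocount of 0.1; ICAM1 was among those 30 (adjusted p = 0.060, range over its alternatives 0.012 to 0.18). DESeq2, edgeR and limma-voom were not run because the tables hold no counts. The library scaling alternatives were applied to the values. At the estimated depth, genes near a value of 1 rest on few fragments, and the depth itself is an estimate.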

Other observations

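The genes in this paragraph and the next were chosen after their values were seen and form no list that was tested. Some genes for contractile and cytoskeletal proteins rose in SLC6A15 cells and others did not pass. Those that rose include the myosin genes MYL9 (160.0 to 273.2, log2 fold change 0.77) and MYH9 (181.6 to 265.8, 0.55), the caveolin gene CAV1 (0.47), the tropomyosin gene TPM4 (0.45) and the myosin light chain kinase gene MYLK (0.40), each past limma's adjusted threshold. TPM2 (0.33, limma adjusted p = 0.058), ACTN1 (0.33, 0.057) and FLNA (0.19, 0.17) were higher without passing, and ACTA2 was at -0.25 (0.17). Genes of the Wnt pathway moved both ways. Besides LGR5, its relative LGR4 (34.0 to 21.5, -0.64) and the receptor genes FZD1 (-0.66) and FZD8 (-0.60) fell, whereas the secreted Wnt inhibitor gene DKK1 (0.87 to 2.39, 0.85) and FZD4 (0.38) rose. The Wnt target AXIN2 was at -0.53 (limma adjusted p = 0.079).

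Some close relatives of the genes with the largest changes moved with them. EDN1 rose (0.44 to 1.90, 0.996) as EDN2 did, CLDN2 fell (4.09 to 1.47, -1.05) as CLDN1 did, and the carbonic anhydrase gene CA2 fell (54.0 to 24.9, -1.09) as CA12 did. The metallothionein genes MT1E (7.07 to 14.0, 0.92) and MT1F (0.22 to 1.57, 1.06) rose. EDN1 and MT1F were below 1 in both Vector libraries and passed the filter through the SLC6A15 libraries alone, so their directions were fixed. The abundant MT2A had values of 872.0 and 1042 in Vector and 1324 and 1729 in SLC6A15 libraries (0.67, limma adjusted p = 0.066), and MT1X was at 0.49 (0.23). Metallothionein sequences are similar, so fragments can be shared between them.

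Tests on growth state, the shift between replicates, ER stress and fibroblasts were chosen only after the result was seen; those on counting noise, length and GC content and scaling were written before. Replicate 2 of each group lay further in the SLC6A15 direction than replicate 1: the replicate difference correlated across genes with the group difference at 0.345 in Vector and 0.42 in SLC6A15 cells, and the 2 replicate differences with each other at 0.387, where genes are not independent. Counting noise does not explain it, since among 1657 genes with a mean value of 50 or more the latter correlation was 0.677, and neither does a trend on transcript length and GC content, since it was 0.405 after removing that trend and 0.394 before, over 11319 genes. The median of the proliferation genes was higher in replicate 2 of both groups than in 10000 random lists matched on expression (lower percentile 100), but random lists do not carry the correlation among these genes (0.953 as estimated), and 7 other lists, among them NF-kappaB, glycolysis and hypoxia and matrix protein genes, also lay outside the central 95% in both groups. Growth state therefore cannot be told apart from another cause of a shared shift, such as a day or batch, which the labels do not give. Lists whose shift exceeded the group difference in the same direction included heat shock and matrix protein genes in both groups, and proliferation and glycolysis and hypoxia genes in Vector cells.

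The rise of ATF4 targets was set against other explanations. The shift between replicates moved the list's median by at most 0.00806 against 0.321 between groups, which argues against it for the list as a whole. Single members such as SLC7A5 and SLC3A2 did shift. ER stress genes had a median of -0.051, already known when that test was chosen. It shows that the listed genes did not rise as a set and cannot exclude ER stress that leaves them unchanged. The other scalings moved the median of all genes only to 0.0036 and -0.017 and left at least 0.314 for the list. They are thus too small to be the cause. Removing the trend on length and GC content left 0.346, which argues against that trend as the cause. A difference between the stable selections that has nothing to do with the transgene stays open and untested, since the labels do not give the number of selections.

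Several epithelial markers fell while PDGFRB and PDPN, also fibroblast markers, rose. Fibroblasts in the SLC6A15 cultures would bring their abundant transcripts. The highest log2 fold change among COL1A1, LUM and FBLN1 was -0.279. These were chosen after their values were seen, and of 6 measured fibroblast markers 3 had a positive and 3 a negative difference. LUM (14.9) and FBLN1 (51.7) were already expressed in Vector cells, so their fall cannot exclude added fibroblasts. COL3A1 was listed at 0 in each library, which gives no sign of fibroblasts that express it. The shift between replicates moved the epithelial median by at most 0.0241 against -0.329 between groups, although the median was -0.103 without Vector replicate 1 and -0.199 without Vector replicate 2, where 10 of the 12 markers passed the filter. Without a filter on low values the epithelial median was -0.041. A change of state within the KTC1 cells, fibroblasts that lack COL3A1 and a difference between the stable selections stay open. No test here separates them.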
